A study of Gallus gallus with 2 samples.

How the data were processed

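RNA from 2 samples of chick limb bud tissue was sequenced, 1 kept with vehicle and 1 with thalidomide, on the Illumina HiSeq 2500 named in the series description. Per the labels, total RNA was extracted and libraries were prepared by a standard Illumina protocol; strand specificity, read length and the annotation release are not given in the sources used here. The submitters' processing notes name bcl2fastq, STAR 2.4.2a, Cufflinks 2.2.1, Cuffdiff and the chicken assembly galGal4, without saying in which step each was used.

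Each deposited file is a gene-level table of FPKM values (fragments per kilobase of transcript, scaled to sequencing depth) with a lower and an upper confidence limit, per the file headers, which the authors made from their reads. FPKM is a normalized value and not a count, so no count test was run. The 17108 annotated genes are the same in both files, and 3418 of them carry no gene symbol. A fragment number was inferred for each gene by reading the distance from FPKM to its upper limit as 2 SD of a count. This gave a whole number, within 0.02, for 87.7% of vehicle and 88.3% of thalidomide genes under 10 fragments. Summed over genes it gave 23361629 fragments with vehicle and 23280002 with thalidomide. Where fragment assignment is uncertain the interval is wider and the inferred number too low, so these totals may be too low. With vehicle, COX1 at 6740 FPKM had 2339 inferred fragments, against 76540 for ND5 at 954 FPKM. Genes near 5 FPKM had a median of 500 fragments with vehicle and 545 with thalidomide, and their limits lay 8.95% and 8.57% from the value; near 50 FPKM the limits lay 3.76% and 3.55% away. These intervals cover counting and assignment error only. In 1183 genes the worth of 1 fragment in FPKM was 0.949 times as large with thalidomide as with vehicle (median).

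Genes that share a symbol (129 symbols) were summed, which left 16756 genes, and the 10915 with an FPKM of at least 1 in at least 1 library were kept. The log2 ratio of thalidomide over vehicle was taken after adding 1 to each FPKM, so that folds are on the FPKM + 1 scale, and its error was propagated from the deposited limits. With 1 library per treatment no test, p-value or replicate SD is possible. Genes were counted at 2-fold, and list members also at 1.5-fold. Before the data were examined, 37 gene lists were fixed. Of their 1411 entries, 1154 matched a gene in the files, 53 of these through an older symbol in the RefSeq gene table of assembly GRCg7b, from which no coordinates were taken. For each list the median log2 ratio was placed among the medians of 10000 random lists of the same size, matched gene by gene on mean abundance in 20 bins. A list with 5 or more measured members stood apart when its median fell outside the middle 95%. This sets the list beside other genes of the same libraries and is not a test between treatments.

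Named genes were chosen by a rule fixed before the data were examined. They are the 12 highest and 12 lowest ratios among symbol-bearing genes with an FPKM of 5 or more in at least 1 library, 2 to 4 extreme members of each list described, the 2 most abundant members of lists for other cell types, and CRBN, SALL4, FGF8, FGF10, SHH, BMP4, VEGFA, KDR, Sox9 and MYOD1 whatever their values. Of the extreme ratios, 23 of 24 were at loci under 300 bases, so the text describes a few of them as examples, and the same choice was repeated among longer loci after the values were seen. Not every gene that the rule picked is reported here. Coordinates are those of the files, counted from 1. No genome sequence or annotation of this assembly was used here, so GC content and exon structure were not examined.

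The ratio and the count at 2-fold were tested on simulated libraries of 10915 genes drawn at the inferred fragment numbers with counting noise only. The changed genes were drawn only from those with a mean of 5 FPKM or more at loci of 300 bases or more. Of 50 genes changed 1.5-fold, 0 passed 2-fold, and of 50 changed 2-fold, 10 passed. Of 50 changed 3-fold and 50 changed 4-fold, 100% passed. Recovery of changed genes under 5 FPKM, where adding 1 shrinks folds more, was not simulated. The list comparison was also run repeatedly on the fixed lists after the real log2 ratios had been shuffled among genes of the same abundance bin. It put 5.95% of 185 such lists outside the middle 95%. Alternatives fixed beforehand were a pseudocount of 0.1, no filter, a filter of 5 FPKM, centring on the median of all genes, rescaling without mitochondrial and haemoglobin genes, annotated loci left unsummed, separate confidence intervals and random lists without matching. Added after the data were seen were leaving out loci under 300 bases, rescaling both libraries to a common FPKM total and matching random lists on length as well, with inferred fragments per FPKM standing in for transcript length in 5 bins within 10 bins of abundance. Uncertain assignment lowers this length proxy in some genes, so the match on true length is incomplete. The common FPKM total was larger than either deposited total, while the added 1 and the filter of 1 FPKM were left unchanged. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.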

Results

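Gene expression was measured by RNA sequencing in 2 libraries of chick limb bud, the outgrowth of mesenchyme under an ectodermal covering from which the limb forms. Buds at Hamburger-Hamilton stage 22 (day 4) had been cut up, and the pieces were kept for 4 h at 37 °C with either vehicle (5% DMSO) or thalidomide at 40 µg/ml. Thalidomide is a sedative that causes limb malformations and binds cereblon, the substrate receptor of a ubiquitin ligase. Each treatment had 1 library, so there are no replicates, no difference has a replicate check, and every value describes these libraries and not the treatments in general. The labels do not state whether the thalidomide pieces also received DMSO. The deposited values are FPKM. Read as counting error alone, their confidence intervals give a total of 23361629 inferred fragments with vehicle and 23280002 with thalidomide. These totals may be too low, since uncertain assignment also widens the intervals. Of 17108 annotated genes, 10803 reached an FPKM of 1 with vehicle and 10773 with thalidomide. The FPKM values summed to 426632 with vehicle and 384280 with thalidomide. Mitochondrially encoded transcripts took 8.94% of the vehicle total and 11.3% of the thalidomide total. A ± after a log2 ratio is the error propagated from the deposited intervals, which covers counting and fragment assignment within a library only.

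The comparison asks which transcripts differ between limb bud tissue kept with thalidomide and with vehicle. Replication genes such as MCM5, a subunit of the replicative helicase, were lower in the thalidomide library, as were cartilage genes such as MATN1 (the matrix protein matrilin-1) and the immediate early gene JUN, which encodes a subunit of the AP-1 transcription factor. Genes of the unfolded protein response and mitochondrially encoded mRNAs were higher. These differences were small: 98.1% of the 10915 genes with an FPKM of at least 1 in either library lay within 1.5-fold, and Pearson's r of log2(FPKM + 1) across these genes, which are not independent replicates, was 0.983. The median log2 ratio of thalidomide over vehicle, taken with 1 added to each FPKM, was −0.05 with quartiles of −0.19 and 0.11. Adding 1 understates the ratio of low genes.

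At least 2-fold higher with thalidomide were 23 genes and at least 2-fold lower were 37. Of these, 19 and 30 are annotated loci spanning under 300 bases, mostly small nucleolar RNAs and microRNA precursors. An example is SNORD35, a small nucleolar RNA, which had an FPKM of 181.7 from about 1 fragment with vehicle and is listed at 0 with thalidomide. The let-7f precursor, gga-let-7f, had an FPKM of 133.7 with vehicle and is listed at 0 with thalidomide, and gga-mir-6555 is listed at 0 with vehicle and had 37.5 with thalidomide. Among the 12 highest and the 12 lowest ratios of named genes with an FPKM of 5 or more, 23 of the 24 were such short loci, none with more than 53.8 fragments in either library. In simulated libraries of the same inferred depth with no change and with counting noise only, which leaves out differences between tissue samples, 37 of 119 short loci passed 2-fold and 0 of 10596 longer loci did. In the real libraries the log2 ratios spread further than counting noise: for 4859 genes with 1000 or more fragments in both, their robust SD was 0.20 and the median counting error 0.04. Of the longer loci, 4 were at least 2-fold higher and 7 lower, which the simulation cannot set apart from such spread. With both libraries rescaled to the same FPKM total, the 2-fold counts were 50 higher and 41 lower, and the median log2 ratio of all genes moved by 0.14. That total was larger than either deposited total, so 11998 genes passed the filter in place of 10915. The added 1 also shrank the ratios of low genes less. These 2-fold counts therefore do not reflect the shift between the libraries alone.

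Among longer loci, a grouping chosen after the values were seen, the highest ratio of a symbol-bearing gene with an FPKM of 5 or more belonged to ENO2, the enolase typical of neurons, with 22.8 FPKM in the vehicle library and 56.9 in the thalidomide library (log2 ratio 1.28 ± 0.03). In the galGal4 assembly named in the submitters' processing notes it lies on chromosome 1 from 76766963 to 76776197. SLC25A42, a mitochondrial coenzyme A carrier (chromosome 28, 3410986 to 3425610), had 2.53 and 6.29 FPKM (1.05 ± 0.10). RBM5, an RNA-binding regulator of splicing (chromosome 12, 3145246 to 3161321), had 42.8 and 83.8 FPKM (0.95 ± 0.02), and NCOR1, a corepressor of nuclear receptors (chromosome 19, 6464906 to 6519844), had 7.26 and 14.9 FPKM (0.95 ± 0.03). Next came the scaffold genes MPP3 and MAPK8IP3, both at 0.78, the kinase MAP4K5 and cat-1, the files' symbol for the cationic amino acid transporter SLC7A1, both at 0.76. ADAMTSL2, a secreted matrix-associated protein, had 0.74, while the transcription factor RFX7 and the nuclear receptor coactivator NCOA3 both had 0.73 and LDLRAD1 had 0.72.

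The lowest ratios of symbol-bearing genes at longer loci, also with an FPKM of 5 or more in at least 1 library, were those of GKN2, a gastrokine (chromosome 22, 260571 to 263926), with 5.84 FPKM in the vehicle library and 2.08 in the thalidomide library (−1.15 ± 0.16), and ROMO1, a small mitochondrial membrane protein annotated at 2 loci that were summed, with 40.4 and 18.5 FPKM (−1.09 ± 0.13). MATN1 (chromosome 23, 243866 to 259904) had 9.06 and 4.39 FPKM (−0.90 ± 0.08). JUN (chromosome 8, 25267213 to 25268157) had 881 and 482 FPKM (−0.87 ± 0.01), and MCM5 (chromosome 1, 51939574 to 51947830) had 55.9 and 33.2 FPKM (−0.74 ± 0.03). HINT2, a mitochondrial hydrolase, and NRGN, a calmodulin-binding neuronal protein, both had −0.71. GALNT9, TSNARE1 and the homeobox gene IRX6 each had −0.69. CYTL1, a secreted protein of cartilage, had −0.67, and OSF-2, the files' symbol for the matrix protein periostin, had −0.66.

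**Figure D1:**
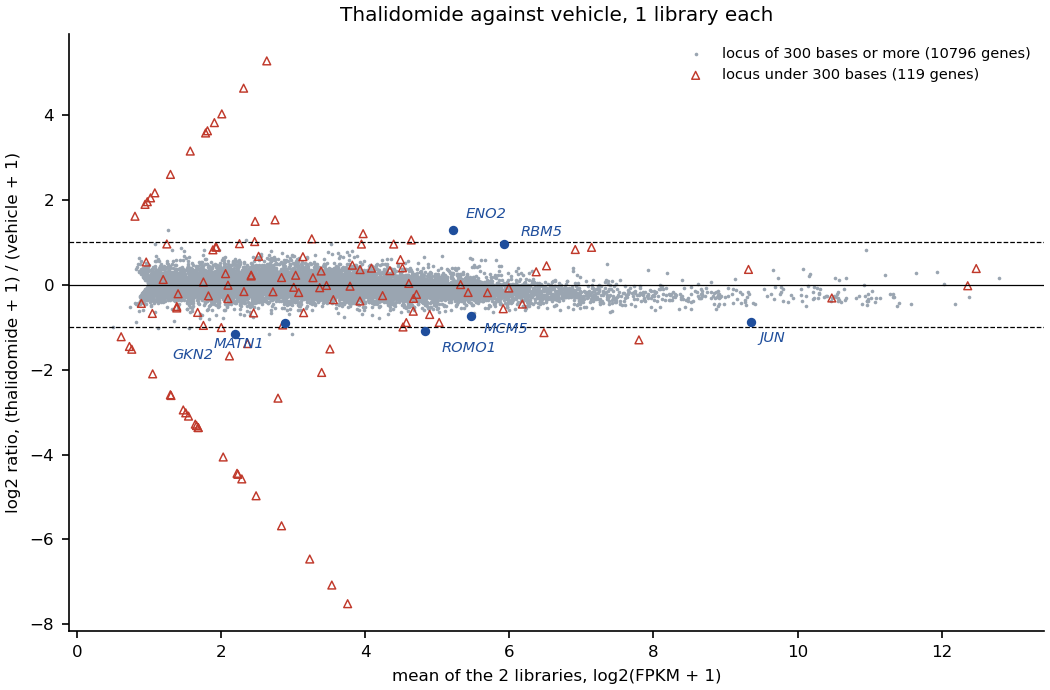
Each point is 1 of the 10915 kept genes, with the mean log2(FPKM + 1) of both libraries on the horizontal axis and the log2 ratio of thalidomide over vehicle on the vertical axis; triangles mark the 119 loci under 300 bases and dashed lines mark 2-fold. Most points past 2-fold are triangles (19 of 23 above, 30 of 37 below), and blue points mark named longer loci such as ENO2 at 1.28 and JUN at −0.87.

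Gene lists fixed before the data were examined were then compared. Of 37 lists, 18 had a median log2 ratio outside the middle 95% of 10000 random lists of the same size and abundance. If list genes varied independently, 1.85 lists would fall outside. Genes of a list may vary together between any 2 tissue samples, and 52 of the 1100 list genes are in more than 1 list. The number 18 therefore does not measure an excess over chance. These lists are said below to stand apart, 3 above and 15 below their random lists. With random lists matched on a fragment-based proxy of transcript length as well, 14 stood apart, 3 above and 11 below. The proxy and abundance both went with the ratio. Across 10077 genes, Spearman's rho of the log2 ratio was 0.268 with a fragment-based length proxy and −0.296 with mean abundance. Over all lists, 4 genes were at least 1.5-fold higher (EDEM1, MDM4, PHLPP2 and cat-1) and 15 at least 1.5-fold lower. Rescaled to the same FPKM total, these counts were 19 and 6, and the lists that did not stand apart had medians above 0, except for the oxidative stress and neural lists.

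**Figure D2:**
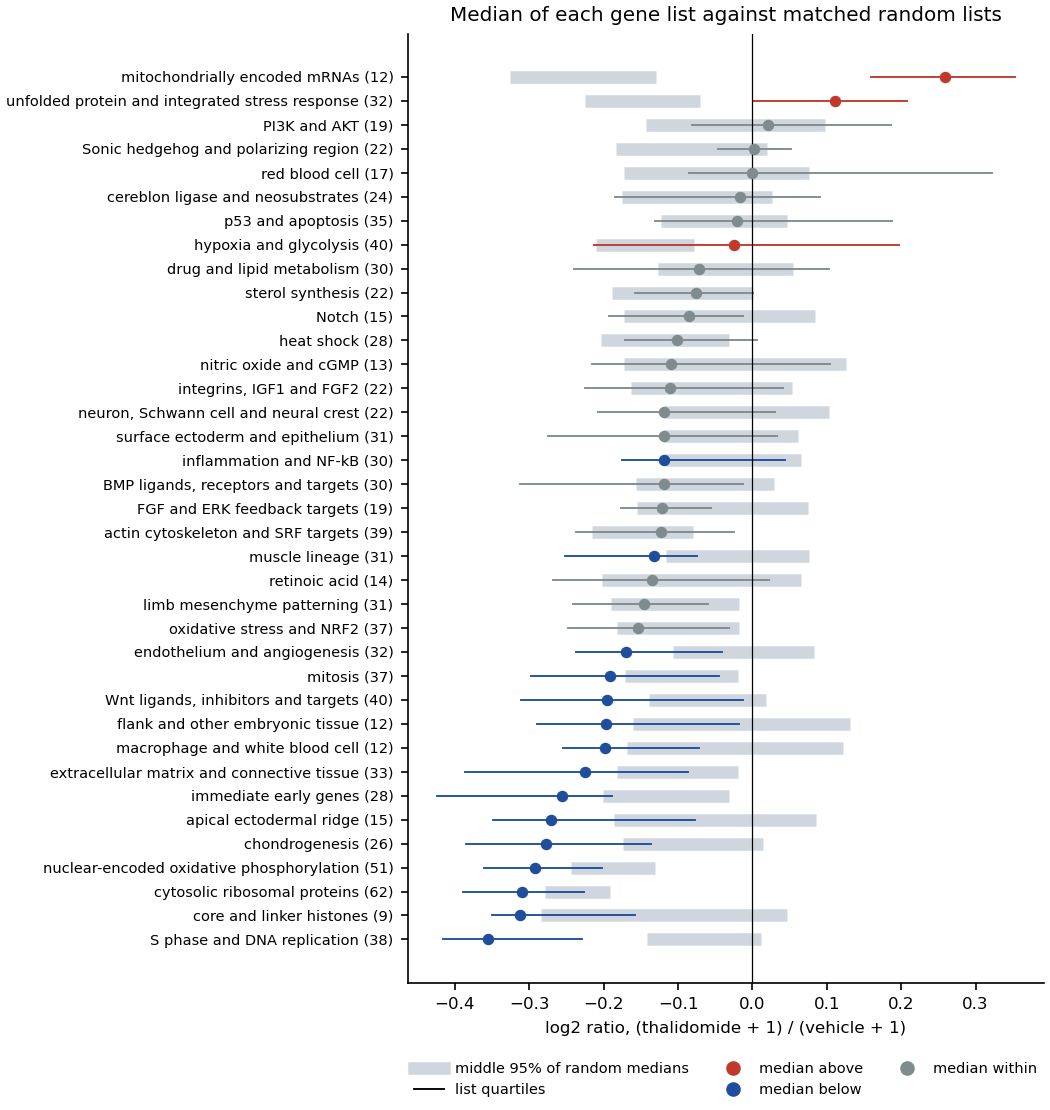
Points give the median log2 ratio of thalidomide over vehicle (1 library each, 1 added to each FPKM) of the 37 gene lists, with the number of measured genes in parentheses, thin lines their quartiles, and grey bars the middle 95% of medians of random lists matched on abundance. The S phase list lies lowest at −0.35, and the mitochondrially encoded mRNAs lie highest at 0.26.

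Genes of S phase and DNA replication were lower with thalidomide in 37 of 38 measured members, and the list's median of −0.35 (1.28-fold lower) lay below all 10000 random lists, with or without length matching. For 31 members the deposited intervals of both libraries did not overlap, as for 42.4% of all kept genes. After MCM5, the lowest were MCM2, another helicase subunit, with 39.9 and 25.04 FPKM (−0.65 ± 0.03), TK1, the thymidine kinase of the nucleotide salvage pathway, with 33.6 and 21.9 FPKM (−0.60 ± 0.08), and the helicase subunit MCM4 with 36.4 and 24.3 FPKM (−0.57 ± 0.03). CHAF1A, a histone chaperone subunit, was the only member above 0, at 0.10 ± 0.05. Mitosis genes had a smaller median of −0.19 over 37 members, 31 of them lower (percentile 0.66 among random lists). The lowest were BIRC5, the inhibitor of apoptosis survivin, which also acts at the centromere (−0.45), the kinetochore gene NDC80 (−0.44) and the cyclin-dependent kinase CDK1, with 183 and 135 FPKM (−0.43 ± 0.05). All 9 histone genes measured had ratios below 0 (median −0.31, percentile 0.86), but this list lay inside its random lists when length was matched (percentile 4.48). The intervals of both libraries overlapped for HIST1H111R (−0.003 ± 0.18), HIST1H111L (−0.16 ± 0.16), H2AFX (−0.31 ± 0.16) and H3F3B (−0.06 ± 0.04). The lowest members of the histone list were HIST1H2B7 (−0.89), which rested on about 14 fragments with vehicle, and H2AFV (−0.46).

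Ribosomal protein mRNAs and the nuclear mRNAs of the respiratory chain were lower with thalidomide, and respiratory chain mRNAs from the mitochondrial genome were higher. All 62 cytosolic ribosomal protein mRNAs were lower, with a median of −0.31 (percentile 0.03) and the lowest ratios at RPL29 (−0.56 ± 0.01), RPL38 and RPL39 (both −0.49). Nuclear genes of oxidative phosphorylation were lower in 50 of 51 members (median −0.29, percentile 0.005). The lowest were NDUFA4, which encodes a subunit of respiratory complexes (151 and 103 FPKM, −0.54 ± 0.03), rbf, the files' symbol for the ATP synthase gene ATP5I (−0.53), and UQCR10 of complex III (−0.52). mRNAs encoded in the mitochondrion itself were higher in 11 of 12 members, with a median of 0.26 (19.7% higher, above all random lists). ATP8, for an ATP synthase subunit, had 0.38 ± 0.05, the complex I subunit ND5 had 0.36 ± 0.01 and ND3 had −0.06. All 3 lists also stood apart when matched on the length proxy. For the mitochondrially encoded mRNAs this says little about length, since the proxy did not follow it. With vehicle, COX1, of 1548 bases, had 2339 inferred fragments at 6740 FPKM. The shorter ND1, of 975 bases, had 57354 at 1547 FPKM.

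Among stress pathways, the unfolded protein and integrated stress response genes were higher with thalidomide. Of 32 members 24 were higher, with a median of 0.11 (1.08-fold higher, above all random lists, whose middle 95% ran from −0.22 to −0.07). EDEM1, which passes misfolded glycoproteins on for degradation, had 4.32 and 7.13 FPKM (0.61 ± 0.08). CRELD2, a secreted protein of the endoplasmic reticulum stress response, had 37.4 and 50.5 FPKM (0.42 ± 0.03), the chaperone gene HYOU1 had 33.2 and 44.0 FPKM (0.39 ± 0.03) and EIF2AK3, the stress sensor kinase PERK, had 10.7 and 13.8 FPKM (0.34 ± 0.05). The transcription factors ATF4 (−0.11 ± 0.01) and ATF3 (−0.20 ± 0.03) of the same list were lower; they were singled out after their values were seen. Immediate early genes, which cells switch on within minutes of a stimulus, were lower in 25 of 28 members (median −0.26, percentile 0.07). Besides JUN, the lowest were CTGF, a matricellular growth factor gene, with 211 and 134 FPKM (−0.65 ± 0.02), FOS, the partner of JUN, with 213 and 137 FPKM (−0.63 ± 0.03), and the MAP kinase phosphatase DUSP1 with 41.7 and 27.0 FPKM (−0.61 ± 0.05).

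**Figure D3:**
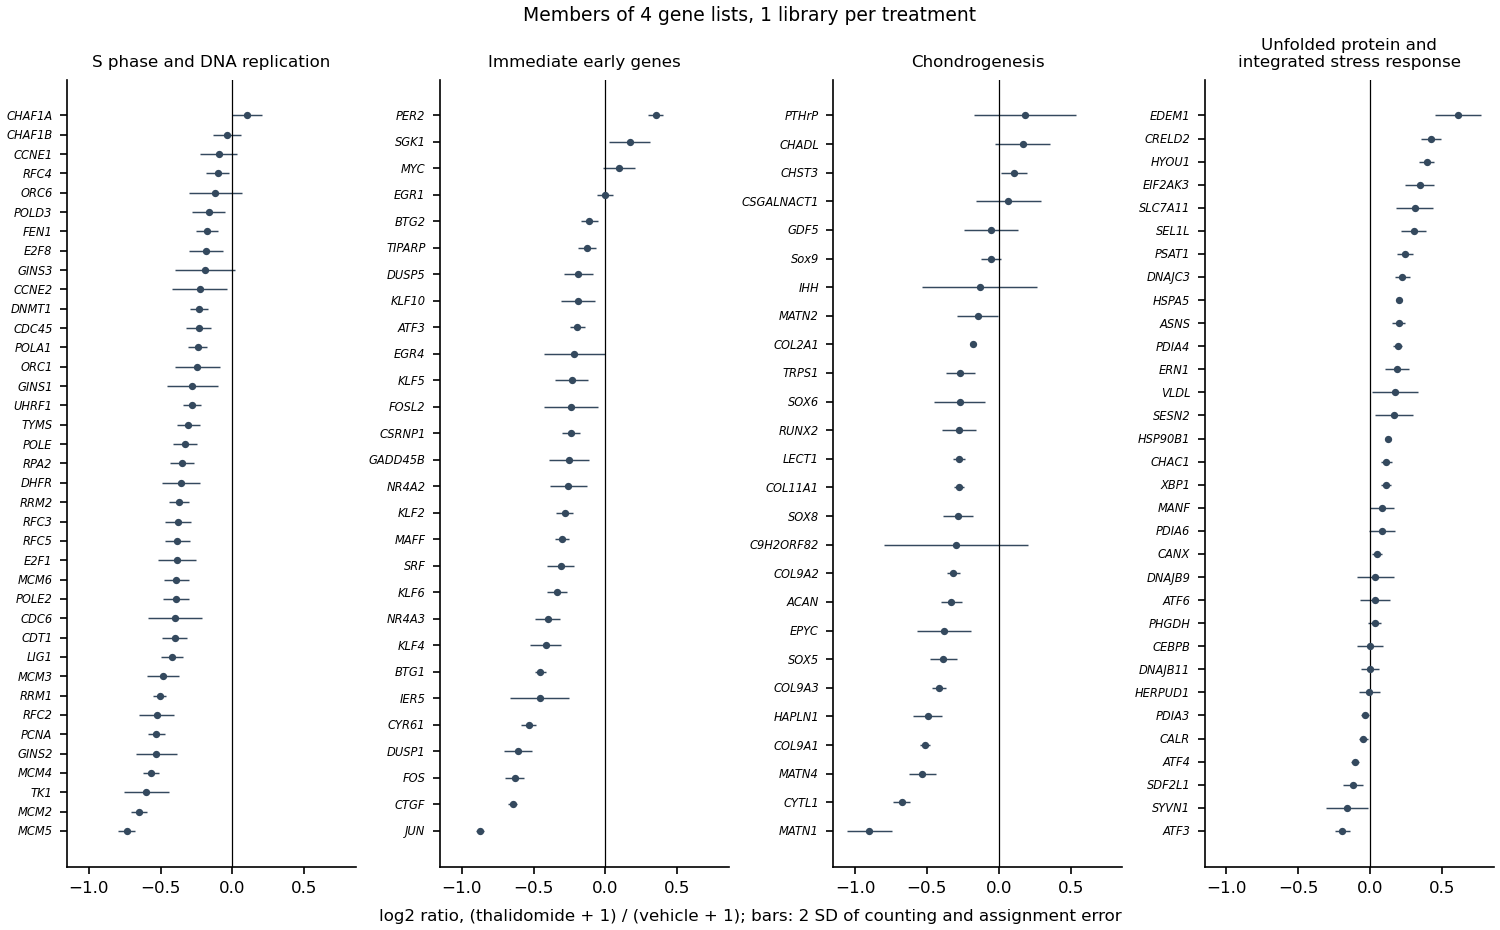
Log2 ratio of thalidomide over vehicle for each measured member of 4 lists, with bars of 2 SD of counting and assignment error from the deposited intervals and no replicate error. S phase members lie left of 0 in 37 of 38 cases, immediate early genes in 25 of 28 and chondrogenesis genes in 22 of 26, while 24 of 32 stress response genes lie right of 0.

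Hypoxia and glycolysis genes went both ways, 18 higher and 22 lower. Their median of −0.02 is below 0, yet it lay above its random lists (percentile 99.94), whose own median was −0.15, and it was above 0 after centring on all genes or rescaling. Against random lists not matched on abundance it did not stand apart (percentile 72.9). The collagen prolyl hydroxylase genes P4HA2 (21.3 and 30.5 FPKM, 0.50 ± 0.04) and P4HA1 (0.40), the oxygen sensor EGLN3 (0.49 ± 0.06) and the phosphofructokinase PFKP (0.43) were highest. GAPDH, the glycolytic dehydrogenase, had 5448 and 4001 FPKM (−0.45), a value singled out after it was seen. The inflammation list was lower (30 genes, median −0.12, percentile 2.16), with NFKBIA, the inhibitor of NF-kB, at −0.43 ± 0.03 and TGFB2, a transforming growth factor, at −0.35. It lay inside its random lists with length matching (percentile 4.15), and its median was above 0 after rescaling. Stress lists that did not stand apart were heat shock (28 genes, median −0.10, percentile 67.1), oxidative stress and NRF2 (37 genes, −0.15, percentile 10.4) and p53 and apoptosis (35 genes, −0.02, percentile 68.4). In these, the inducible chaperone hsp70 had 450 and 301 FPKM (−0.58 ± 0.01) against 0.24 for DNAJB4, a co-chaperone. The glutathione enzymes GPX1 and GSR were both at −0.39, against 0.41 for the exporter ABCC1. MDM4 (0.64 ± 0.07) and MDM2 (0.50 ± 0.07), both inhibitors of p53, stood against BIRC5 and the survival gene MCL1 (−0.33).

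CRBN, which encodes cereblon, had 4.46 FPKM with vehicle and 5.13 with thalidomide (0.17 ± 0.08). SALL4, a zinc finger transcription factor degraded through cereblon in the presence of thalidomide, had 4.18 and 4.98 FPKM (0.21 ± 0.06). As a list, the cereblon ligase and its substrates did not stand apart (24 genes, 11 higher and 13 lower, median −0.02, percentile 87.8). SALL4 and CRBN themselves had its highest ratios, and the lowest were those of the ligase subunit RBX1 (110 and 74.9 FPKM, −0.54 ± 0.05) and RAB28 (−0.36). Protein was not measured, so these mRNA values do not show whether substrates were degraded.

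Of the signals that drive limb outgrowth, FGF8, the growth factor of the apical ectodermal ridge, had 0.775 and 0.765 FPKM (−0.01 ± 0.20) from about 19 fragments in each library, and no difference was detectable at this depth. SHH, the signal of the polarizing region, had 0.777 and 0.505 FPKM (−0.24 ± 0.13) from 41 and 28 fragments, and its intervals overlapped. FGF10, the mesenchymal growth factor that maintains the ridge, had 15.6 and 11.4 FPKM (−0.42 ± 0.08) and BMP4, a bone morphogenetic protein, had 24.9 and 19.97 FPKM (−0.30 ± 0.05). The ridge list was lower in 13 of 15 members (median −0.27, percentile 0.04), but without the filter on low abundance its median was −0.13 and lay inside its random lists (percentile 4.70). Its lowest members, DLX5 (29.0 and 18.5 FPKM, −0.62 ± 0.06), MSX2 (32.6 and 21.9 FPKM, −0.56 ± 0.04) and DLX6 (−0.46), are homeobox genes that limb mesenchyme also uses. The Wnt list was lower in 31 of 40 members (median −0.20, percentile 0.03). FRZB, a secreted Wnt inhibitor, had 86.1 and 59.9 FPKM (−0.51 ± 0.03), the R-spondin receptor LGR5 had −0.45, the ligand Wnt6 −0.44 and the inhibitor DKK2 −0.38, so that inhibitors as well as a ligand and a receptor were among the lowest.

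Other patterning lists did not stand apart. Hedgehog genes were divided evenly (22 genes, 11 higher and 11 lower, median 0.00, percentile 95.1), from HHIP, a Hedgehog-binding inhibitor (−0.35 ± 0.09), to the BMP antagonist GREM1 (0.22 ± 0.17). Limb mesenchyme genes had a median of −0.15 over 31 genes (percentile 17.4), with the transcription factors TWIST1 (86.3 and 60.6 FPKM, −0.50 ± 0.04) and MSX1 (−0.45) lowest and TBX5, a T-box gene of the forelimb, highest (0.22 ± 0.03). BMP genes had −0.12 over 30 genes (percentile 13.6), with SMURF1, a ubiquitin ligase for SMAD proteins, highest at 0.33 and DLX5 and MSX2 lowest. FGF and ERK feedback genes had −0.12 over 19 genes (percentile 8.10), with the receptor FGFR4 at −0.61 ± 0.03 and the ETS factor ETV4 at 0.14. Retinoic acid genes had −0.13 over 14 genes (percentile 17.7), with the receptors RXRG (−0.49) and RARB (−0.44) lowest and TGM2, a transglutaminase, highest (0.18). Notch genes had −0.09 over 15 genes (percentile 29.4), with HES1, a target of Notch, at −0.30 and NRARP, a feedback inhibitor, at 0.19 ± 0.19.

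Chondrogenesis genes were lower in 22 of 26 members, with a median of −0.28 (1.21-fold lower, below all random lists). After MATN1 and CYTL1 came MATN4, another matrilin, with 74.3 and 51.1 FPKM (−0.53 ± 0.05), and COL9A1, a collagen of cartilage, with 91.5 and 63.8 FPKM (−0.51 ± 0.02). Sox9, the transcription factor that starts cartilage formation, had 21.1 and 20.3 FPKM (−0.05 ± 0.03), and its ratio was above 0 after rescaling. Extracellular matrix and connective tissue genes were lower in 30 of 33 members (median −0.23, percentile 0.10), with LUM, the proteoglycan lumican, at 67.5 and 43.0 FPKM (−0.64 ± 0.03), the transcription factor OSR2 at −0.54 and DCN, the proteoglycan decorin, at −0.53. The actin cytoskeleton list did not stand apart (39 genes, −0.12, percentile 77.2). CTGF and CYR61, a related matricellular gene (−0.53), were its lowest members, and the kinase LIMK2 was its highest (0.45).

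Muscle lineage genes were lower in 26 of 31 members (median −0.13, percentile 1.08), with TMEM8C, the files' symbol for the myoblast fusion gene myomaker, at −0.44 ± 0.15, ACTC1, the cardiac-type actin, at 35.8 and 26.4 FPKM (−0.43 ± 0.03), and MYOD1, the myogenic transcription factor, at 20.2 and 17.1 FPKM (−0.23 ± 0.05). With length matching the percentile was 3.92, inside the random lists, and without mitochondrial and haemoglobin transcripts in the scale the median was above 0. Endothelial and angiogenic genes were lower in 26 of 32 members (median −0.17, percentile 0.04), though their median was at 0 under that same rescaling. ESAM, an endothelial adhesion molecule, had −0.46 ± 0.13, angiopoietin-2 had −0.42 and the cadherin CDH5 had 13.9 and 10.6 FPKM (−0.36 ± 0.04). NRP2, a neuropilin, and the ETS factor ERG, the most abundant members, had −0.20 and −0.19. The growth factor VEGFA had 25.2 and 26.6 FPKM (0.07 ± 0.06), its receptor KDR had 3.64 and 4.11 FPKM (0.14 ± 0.04), and PGF, a related growth factor singled out after its value was seen, had 0.58 ± 0.09.

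Markers of other cell types were followed in the same way. Macrophage genes were lower in 10 of 12 members (median −0.20, percentile 0.77), with the protease CTSS (−0.44 ± 0.12) and the MHC class II gene BLB1 (−0.33 ± 0.11) lowest. The most abundant members were ARHGDIB, with 50.3 and 43.2 FPKM (−0.22 ± 0.04), and the transcription factor IRF8, with 18.7 and 19.97 FPKM (0.09 ± 0.05). PTPRC, the other member above 0, was singled out after its value was seen. It had 0.72 FPKM with vehicle and 1.07 with thalidomide (0.27 ± 0.07). Genes of the flank and other embryonic tissue had a median of −0.20 over 12 genes (percentile 0.75, or 3.04 with length matching and 6.83 without the filter on low abundance, and above 0 without mitochondrial and haemoglobin transcripts in the scale), with the plasma protein genes APOA1 at 27.9 and 26.2 FPKM and TTR at 22.3 and 17.8 FPKM. Neural genes (22 genes, −0.12, percentile 2.55; TUBB3, a neuronal tubulin, −0.28 and TFAP2B −0.21) and surface ectoderm genes (31 genes, −0.12, percentile 2.80; the cadherin CDH3 −0.34 and the keratin KRT19 −0.30) lay just inside their random lists. Red blood cell genes did not stand apart (17 genes, 9 higher and 8 lower, median 0.00, percentile 81.6), but the most abundant, the haemoglobin genes HBG1 (215 and 273 FPKM, 0.35 ± 0.02) and HBAA (137 and 193 FPKM, 0.49 ± 0.04), were higher.

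The remaining lists did not stand apart. Integrin, IGF1 and FGF2 genes had a median of −0.11 over 22 genes (percentile 15.9), from the integrin ITGA4 (−0.46 ± 0.06) to IGF-I, insulin-like growth factor 1, with 10.7 and 14.1 FPKM (0.37). PI3K and AKT genes had 0.02 over 19 genes (percentile 78.7), from the lipid phosphatase INPP4B (−0.48) to PHLPP2, a phosphatase that acts on AKT (0.59 ± 0.05). Nitric oxide and cGMP genes had −0.11 over 13 genes (percentile 14.9), with cat-1 at 0.76 ± 0.06 and the endothelial synthase NOS3 at −0.31 ± 0.14. Sterol synthesis genes had −0.08 over 22 genes (percentile 68.6), from MVD, an enzyme of the mevalonate pathway (−0.31), to the squalene synthase gene FDFT1 (0.33). Drug and lipid metabolism genes had −0.07 over 30 genes (percentile 24.0), from the cytochrome P450 genes CYP1B1 (9.60 and 6.05 FPKM, −0.59 ± 0.07) and CYP7B1 (−0.57) to the exporter ABCG2 (0.32).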

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

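Tests that left out loci under 300 bases, rescaled to a common total or matched on length were not planned and were added once the results they vary had been seen. Of the 18 lists that stood apart, 11 stood apart with the same sign under all of the 10 alternatives that could be computed for them: S phase, mitosis, ribosomal proteins, nuclear oxidative phosphorylation, mitochondrially encoded mRNAs, unfolded protein response, immediate early genes, chondrogenesis, extracellular matrix, Wnt and macrophage. The mitochondrial list has no value once its genes are left out, and the macrophage list has none with a filter of 5 FPKM, which left too few members. The number of lists apart ran from 14 to 19. The 2-fold counts of 23 higher and 37 lower became 7 and 8 where separate intervals were required and 4 and 7 without loci under 300 bases, by the removal of genes; the higher count became 42 with a pseudocount of 0.1, 50 rescaled to a common total and 56 rescaled without mitochondrial and haemoglobin genes. Listed genes at least 1.5-fold higher (4) became 8 with a pseudocount of 0.1, 19 rescaled to a common total and 24 rescaled without those genes, and those 1.5-fold lower (15) became 9 centred, 6 rescaled to a common total and 3 rescaled without those genes. A pseudocount of 0.1 brought the neural (−0.15) and surface ectoderm (−0.15) medians outside their random lists and inflammation (−0.13) inside. Without a filter the ridge (−0.13) and flank (−0.045) lists came inside. A filter of 5 FPKM put Hedgehog (0.016), neural (−0.21) and surface ectoderm (−0.20) outside and histones (−0.31), flank (−0.21) and inflammation (−0.12) inside. Centring turned hypoxia positive (0.024). Rescaling without mitochondrial and haemoglobin genes turned hypoxia (0.16), endothelium (0.00057), muscle (0.021), flank (0.028) and inflammation (0.053) positive and put surface ectoderm (0.042) outside; rescaling to a common total turned hypoxia (0.13) and inflammation (0.016) positive and put the neural list (−0.0028) outside. These sign changes came with the scale, which moved the median of all genes from −0.05 to 0.13 and 0.09. The 2 rescalings also raised the number of genes kept from 10915 to 12101 and 11998. Their effect on the counts and medians was not separated from the shift. With loci left unsummed inflammation (−0.12) came inside. Unmatched random lists put limb mesenchyme (−0.15) and oxidative stress (−0.15) outside and hypoxia (−0.024), muscle (−0.13) and inflammation (−0.12) inside. Leaving out loci under 300 bases put the neural list (−0.12) outside. Length matching put histones (−0.31), muscle (−0.13), flank (−0.20) and inflammation (−0.12) inside. Except where the construction shows it, the cause was not tested. For the 34 named genes followed, 0 ratios that lay beyond 2 interval errors of 0 changed sign; FGF8 and Sox9, within that error, were above 0 after either rescaling. Of the recomputed ratios, 48 moved by more than that error and 212 did not. Depth limits FGF8 and SHH, with 19 and 41 fragments with vehicle. No paired analysis was possible because each treatment has 1 library and there is no test.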

Other observations

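All groupings of genes in this part were chosen after their values were seen, as were the tests on the haemoglobins, the test of scale on the stress response list and those that ask about an effect of the treatment; the tests of length and scale on the S phase list and of length on the stress response list were set once those lists had been seen to stand apart, but before the outcomes of the tests themselves were known. Within the Wnt list, which was lower, 4 feedback inhibitors that canonical Wnt signalling induces were higher. ZNRF3 and RNF43, which remove Wnt receptors from the cell surface, had log2 ratios of 0.42 ± 0.07 and 0.31 ± 0.11, the Dishevelled inhibitor NKD1 had 0.32 ± 0.06 and AXIN2, a scaffold of beta-catenin degradation, had 0.21 ± 0.05. LGR5 (−0.45), Lef-1 (−0.25) and NOTUM (−0.02), also targets, had ratios below 0, so that the 7 targets measured went both ways (median 0.21, with a standard error over members of 0.16, and mean 0.07). Within the stress response list, the chaperones and degradation factors of the endoplasmic reticulum had a median of 0.08, with 12 of 18 genes higher, and the amino acid response genes around ATF4 had a median of 0.14, with 8 of 10 genes higher. For 13 regulators and targets of p53 the median was 0.03, with 9 genes higher and 4 lower.

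The 5.8S ribosomal RNA loci summed to 348 FPKM with vehicle and 141 with thalidomide, an unnamed locus of 1621 bases on the mitochondrial genome had 2181 and 2565 FPKM, and an unnamed locus of 1029 bases on an unplaced scaffold had 1498 and 2615 FPKM. Whether the selection or quality of RNA differed between the libraries, and with it these loci or the mitochondrially encoded mRNAs, was not tested. The 494 genes of chromosome Z had a median log2 ratio of −0.08, and the 6 genes of chromosome W summed to 23.8 FPKM with vehicle and 22.5 with thalidomide.

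S phase and DNA replication genes were lower in the thalidomide library. A trend with the length proxy between the libraries is argued against as the whole cause, since the list's percentile was 0.0 among random lists matched on that proxy. True transcript length was not tested, because assignment error lowers the proxy of some genes. The difference in FPKM total is also argued against as the whole cause. After rescaling to a common total the list's median was −0.23, with a standard error over members of 0.036, although genes are not replicates. That rescaling moved the median of all genes by 0.14, so it speaks to that scale only. After it the list's median differed from that of all genes by −0.32. An effect of the treatment on these genes may account for it, a hypothesis that was not tested. With 1.0 library per treatment it cannot be told apart from a different DMSO content, which the labels leave open. The same holds for a difference in RNA quality, in library preparation or between the pieces of tissue that went into each library.

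Unfolded protein and integrated stress response genes were higher in the thalidomide library. Matching on the length proxy left the list at percentile 100, which argues against a trend with that proxy as the whole cause. True transcript length was not tested, because assignment error lowers the proxy of some genes. Rescaling to a common total raised the list's median to 0.26 and so could not test the scale of the FPKM values. Centred on the median of all genes, the list's median was 0.16, with a standard error over members of 0.040, although genes are not replicates. The median of all genes was −0.05, so centring could only raise the list's median and could not test the scale either. A shared scale moves all genes alike, so the list's distance from other genes depends little on it. An effect of the treatment on these genes could account for it, a hypothesis that was not tested. With 1.0 library per treatment it cannot be told apart from a different DMSO content, which the labels leave open. The same holds for a difference in RNA quality, in library preparation or between the pieces of tissue.

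Haemoglobin mRNAs were higher in the thalidomide library, with a median log2 ratio of 0.35 over 6 genes and a standard error over members of 0.090, although the intervals of HBG2 (0.06 ± 0.06) and HBE1 (0.34 ± 0.14) overlapped between the libraries. A larger share of red blood cells may seem a candidate explanation. However, 4 membrane protein genes largely specific to red cells (SLC4A1, SPTB, RHD and TSPO2, at 181 or more fragments per library) had a median of −0.040. That median lay below the haemoglobin median by more than its standard error over members, 0.052. Genes are not replicates, and adding 1 shrinks the ratios of genes as low as these 4. A larger share of red cells is therefore not excluded. The wider set of 11 other red cell genes had −0.08. Rescaling to a common total raised the haemoglobin median to 0.55 and so could not test the scale of the FPKM values. Centred on the median of all genes, the haemoglobin median was 0.39, against the standard error of 0.090. Centring could only raise this median too, because the median of all genes was −0.05, so it could not test the scale either. A difference in haemoglobin mRNA within red cells, or free haemoglobin RNA from burst cells, stays open and was not tested.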
